A study of Sorghum bicolor with 6 samples.

How the data were processed

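Flag leaf RNA of 3 sorghum germplasm lines was sequenced under 2 water regimes. Per the labels' protocols, plants were grown in pots, drought began at 25 days, and the soil held 15% to 20% water in well-watered and 5% to 8% in drought-stressed pots. Libraries were made with a stranded mRNA kit and sequenced on an Illumina HiSeq instrument, with 3 plants per library per the labels. The lines were told apart by the germplasm label, and the regime by the treatment label.

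The authors deposited 1 table per gene (32944 rows) and 1 per transcript (50095 rows), each with read counts, FPKM and TPM for the 6 libraries. The deposited read counts are estimated counts, already whole, so no further rounding was needed. They equalled the deposited FPKM times transcript length times a factor per library, rounded up, in 99.0% to 99.1% of the transcripts with a value, and within 1 count in 100%. They thus look derived from coverage, but the match does not show which value came first. Their scale depends on a counting tool that is not given in the sources used here, nor is the aligner. The deposited FPKM values are scaled for transcript length and library size, and the deposited TPM values sum to 999812 to 999937 per library. Gene counts were the sums over transcripts in 100% of values. A value of 0 can be a failed estimate. The edgeR package is listed in the submitters' processing notes with no version and no step. The tables use the Sorghum_bicolor_NCBIv3 assembly, and coordinates come from a table of RefSeq genes of that assembly, in which all 32944 genes were found by gene number. Whether counting used the strand is not given in the sources used here.

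Library totals ran from 16962422 to 30145550 counts. A floor of 3 counts corresponds to 0.068 to 0.207 CPM. Ribosomal RNA rows (11) were kept in the tests, and TMM normalisation factors ran from 0.814 to 1.49. Intervals and floors cover counting error only, at a confidence level of 95% (exact binomial).

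Analyses ran in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were kept with edgeR's filterByExpr on the water regime at its defaults (minimum count 10, minimum total 15), which left 18800. Counts were scaled with TMM and fitted with edgeR's quasi-likelihood model, robust, with line and regime as terms, and Benjamini-Hochberg adjustment at 0.05. This leaves 2 residual degrees of freedom. The drought term is the difference shared by the lines, and its error is the remainder between lines. Contrasts between lines came from the same fit. Standard errors were taken from the fold change and its F statistic. The replicate block is the line, since both libraries of a pair come from the same germplasm. The deviations from the regime means correlated, across genes, at 0.417 within the early, 0.615 within the intermediate and 0.659 within the late pair, and each library correlated best with its own line. No label says whether libraries within a regime are otherwise independent, so p-values measure only the spread between these samples.

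Within a line, log2 ratios of CPM with a prior count of 2 were described without a test, with genes at least 2-fold higher or lower counted. Agreement between lines was described by correlations across genes and by overlaps set against independent lists. The 29 gene lists, matched on gene descriptions, were tested with limma's camera at a correlation of 0.01, with an estimated correlation and the fry rotation test as alternatives. The lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. Lists between lines, the removal of ribosomal RNA and organelle rows, the removal of genes at 0, the fit without both early libraries, total counts for the lines, and an estimated correlation with a pair left out were added after seeing the data.

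Genes were named by rule. For drought, the rule took described genes with a mean of at least 5 CPM and the same sign in all lines, up to 12 per direction among those past the threshold, or filled to 6 with the smallest p where fewer passed. For each list it took the 4 members with the smallest p. Within lines and between lines it took the 5 largest differences per direction among described genes with at least 5 CPM on average, and for the lines also 4 members of the circadian and flowering list. YSL12, NDR1/HIN1-like protein 13, the dhurrin genes and the clock genes in the closing section were chosen after their values were seen.

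The fits were tested on simulated counts with the means and sizes of these libraries. For drought, 21.0% of genes changed 4-fold, 68.1% changed 8-fold, 90.0% changed 16-fold and 96.4% changed 64-fold were recovered over 17824 genes, and 43 of 430 calls were false. For the late against the early line, 3.6%, 25.9%, 65.7% and 91.5% were recovered at the same folds over 17856 genes, and 29 of 291 calls were false. For camera, a list of 50 genes shifted 2-fold was called in 10 of 10 rounds and unshifted lists in 0 of 280 over 18800 genes. Only the preset correlation was tried, on random lists of genes drawn independently of each other. Real lists can be correlated, with an estimate of 0.683 for light reactions. The 0 of 280 thus does not show how often correlated lists are called falsely.

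Alternatives covered RLE size factors, DESeq2, limma-voom, other low-count filters, a fit that is not robust, limma on log2(FPKM + 1) and log2(TPM + 1), the transcript table, no replicate block, no regime term, leaving out pairs or single libraries, other prior counts and other fold limits.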

Results

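RNA was sequenced from flag leaves, the last leaf below the panicle, of 3 sorghum (Sorghum bicolor) germplasm lines from a seed gene bank that differ in flowering time. The early line is FRANCE 6005, the intermediate line KURUNEGALA 421 and the late line MONARAGALA 93. Each line gave 1 well-watered and 1 drought-stressed library, so each water regime holds 3 libraries and each line 2. The leaves were taken at pollen shedding. Drought began at 25 days in every line, so lines that differ in flowering time may have differed in age and length of drought at harvest. Neither can be told apart from the line here. The deposited tables list 32944 genes of the Sorghum_bicolor_NCBIv3 assembly, of which 7308 had no counts in any library and 18800 were tested. No combination of line and regime was repeated, so p-values rest on how far the lines differ in their drought ratio.

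The libraries held 16962422 (early, drought-stressed) to 30145550 (late, well-watered) estimated read counts. Ribosomal RNA, mostly plastid 23S, took 38.7% of the early well-watered library, 37.9% of the early drought-stressed library, 25.4% and 21.8% of the intermediate libraries, and 2.36% and 4.0% of the late libraries, in the same order of regime. The share was 22.1% ± 18.4 (SD, n = 3) in the well-watered and 21.2% ± 17 (SD, n = 3) in the drought-stressed libraries, so it followed the line and not the regime. Plastid genes other than ribosomal RNA took 0.379% to 1.06% of the counts. On the log2 scale, the line accounted for 69.6% of the variance over the tested genes and the water regime for 10.8%. The remainder, with 2 residual degrees of freedom, took 19.6%, so the share of the regime does not stand out from it. The Spearman correlation across genes between the pair of libraries of a line was 0.955 in the late line and 0.934 in the intermediate line, but 0.819 in the early line, where it was close to the 0.808 between the drought-stressed early and intermediate libraries.

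**Figure D1:**
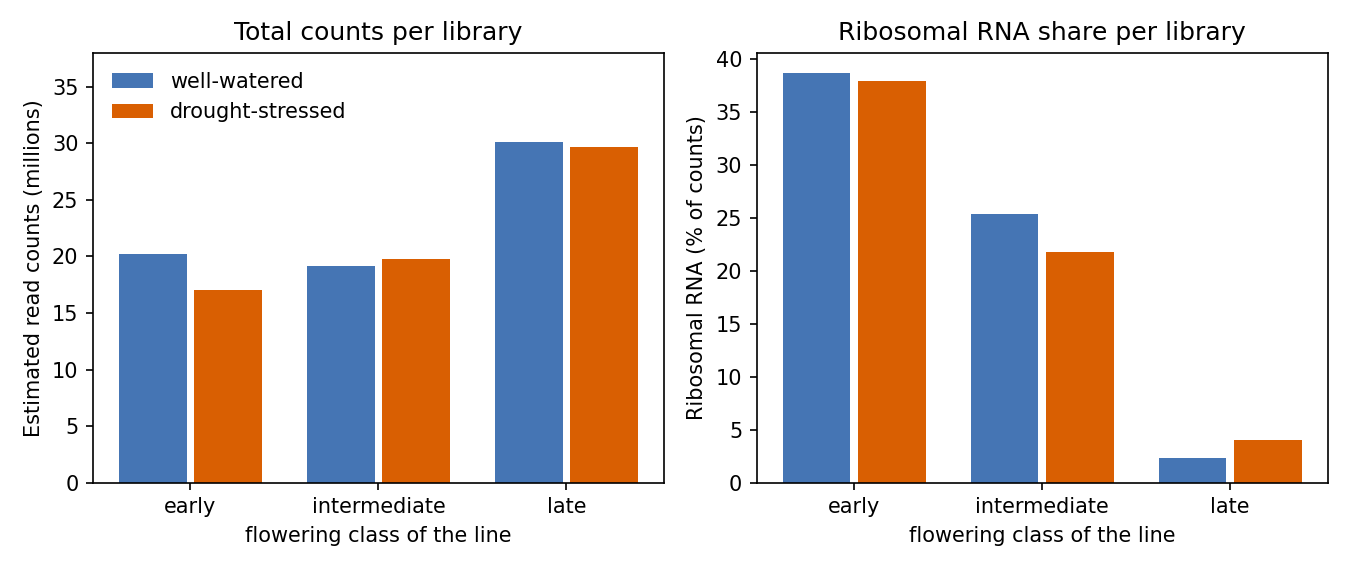
Total estimated read counts (left) and the share of counts from ribosomal RNA in percent (right), 1 bar per library, by line and water regime. The early libraries hold 38.7% and 37.9% ribosomal RNA and the late ones 2.36% and 4.0%.

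The first comparison asked which genes differ between drought-stressed and well-watered flag leaves across the 3 lines. Abscisic acid 8'-hydroxylase 1 (LOC8073163, chromosome 4, 61294605 to 61297468), which breaks down the drought hormone abscisic acid, had 143 ± 68.1 CPM (counts scaled to a common library size) under drought and 27.5 ± 3.71 when watered (SD, n = 3 each), with log2 ratios of 2.07 in the early, 1.99 in the intermediate and 2.80 in the late line. Transcription factor PIF5 (LOC8086399, chromosome 2, 2831373 to 2835393), a relative of the phytochrome-interacting factors, had ratios of 5.03, 4.42 and 2.63. Early light-inducible protein HV90 (LOC8060733, chromosome 2, 4934989 to 4935985), a thylakoid protein made under excess light, had 4.04 ± 3.73 CPM under drought and 35.2 ± 27.0 when watered, with ratios of -2.72, -4.57 and -1.19. 12-oxophytodienoate reductase 1 (LOC8070772, chromosome 10, 7170614 to 7172131) had 9.32 ± 4.55 CPM against 26.7 ± 4.55, with ratios of -2.31, -1.18 and -1.37.

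No gene passed an adjusted p of 0.05 in edgeR's quasi-likelihood test with the line as a block (0 higher, 0 lower of 18800; smallest adjusted p = 0.984). At an unadjusted p under 0.05 there were 538 genes, where 940 are expected by chance. limma-voom called 0 genes too, while DESeq2's Wald test called 20 higher and 5 lower. Its calls included PIF5 (LOC8086399, DESeq2 adjusted p = 3.88e-07) and the abscisic acid 8'-hydroxylase (LOC8073163, DESeq2 adjusted p = 6.70e-05). On simulated counts of this design, the edgeR test recovered 21.0% of genes changed 4-fold and 90.0% of those changed 16-fold, so its power for smaller changes was low. The simulation gave a gene the same dispersion in every pair. In the data, the log2 ratios had an SD of 1.76 in the early, 1.17 in the intermediate and 0.79 in the late pair. Power may thus have been lower than simulated for large changes too: PIF5, 18.5-fold higher by the fit, did not pass.

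The genes named above are among the 6 in each direction with the smallest p, none of which passed. The others with higher values under drought were U-box domain-containing protein 19 (LOC8056192, log2 fold change 3.02 ± 0.46 SE), LOB domain-containing protein 1 (LOC8081443, 4.06 ± 0.65), the chloroplast chaperone dnaJ 11 (LOC8064995, 2.24 ± 0.38) and a probable 2-oxoglutarate-dependent dioxygenase (LOC8057750, 2.11 ± 0.37). The others with lower values were a tropinone reductase homolog (LOC8082051, -1.51 ± 0.34), RNA-binding protein 3 (LOC8084186, -2.20 ± 0.58), a glycine-rich cell wall structural protein (LOC110430477, -1.79 ± 0.47) and dymeclin (LOC8079277, -1.26 ± 0.34).

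Genes of the light reactions and of pathogen defence had lower medians under drought in the early pair, but not in every other pair. The 48 tested genes of the photosynthetic light reactions had a median log2 ratio of -1.33 in the early, -0.25 in the intermediate and 0.52 in the late line, and 37 of them were at least 2-fold lower in the early line against 3 in the intermediate and 0 in the late line. The 93 pathogen defence genes, among them chitinases, thaumatin-like proteins and germin-like proteins, had medians of -2.13, 0.67 and -0.34, with 57 members at least 2-fold lower in the early line and 34 at least 2-fold higher and 8 at least 2-fold lower in the intermediate line. The 43 genes of carbon fixation and the C4 cycle had medians of -0.58, -0.40 and 0.03. Within that list Rubisco activase (LOC8086040), which keeps Rubisco in its active form, had ratios of -4.85, -2.45 and -0.95, and a regulatory protein of pyruvate, phosphate dikinase (LOC8080149) had -1.69, -2.13 and -0.62.

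Of the 29 gene lists, 5 were called lower by camera with a preset correlation of 0.01, namely light reactions (adjusted p = 0.003), pathogen defence (0.0042), carbon fixation (0.009), WRKY transcription factors (0.029) and antioxidant enzymes (0.045). With an estimated correlation, none of the 5 was called (adjusted p = 0.942 for each with an estimated correlation), and fry called 0 lists. The estimated correlation between genes was 0.683 for light reactions, 0.262 for defence and 0.073 for carbon fixation. It was 0.089 for WRKY and 0.003 for antioxidant enzymes, against the preset 0.01. For antioxidant enzymes the estimate thus lay below the preset value, yet the unadjusted camera p rose from 0.0078 to 0.083. Camera with an estimated correlation rests on the 2 residual degrees of freedom, and its power was not simulated. Lost calls therefore do not show that correlation between genes made the preset ones. No member of any list passed over all genes, and none passed when adjusted over the list alone. Without the early pair, the light reactions and defence lists turned to the higher side and were not called (adjusted p = 0.52 and 0.369). The calls of carbon fixation (adjusted p = 0.0757) and WRKY (0.329) also ended without that pair, and those of WRKY (0.194) and antioxidant enzymes (0.479) without the late pair, and of carbon fixation (0.112) and antioxidant enzymes (0.135) without the intermediate pair. The WRKY medians were -0.72, 0.02 and -0.26 over 61 genes, and those of the 94 antioxidant genes -0.24, 0.00 and -0.19. Among the latter, glutathione S-transferase GSTU6 (LOC8062884) had ratios of -3.41, -2.66 and -1.24.

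**Figure D2:**
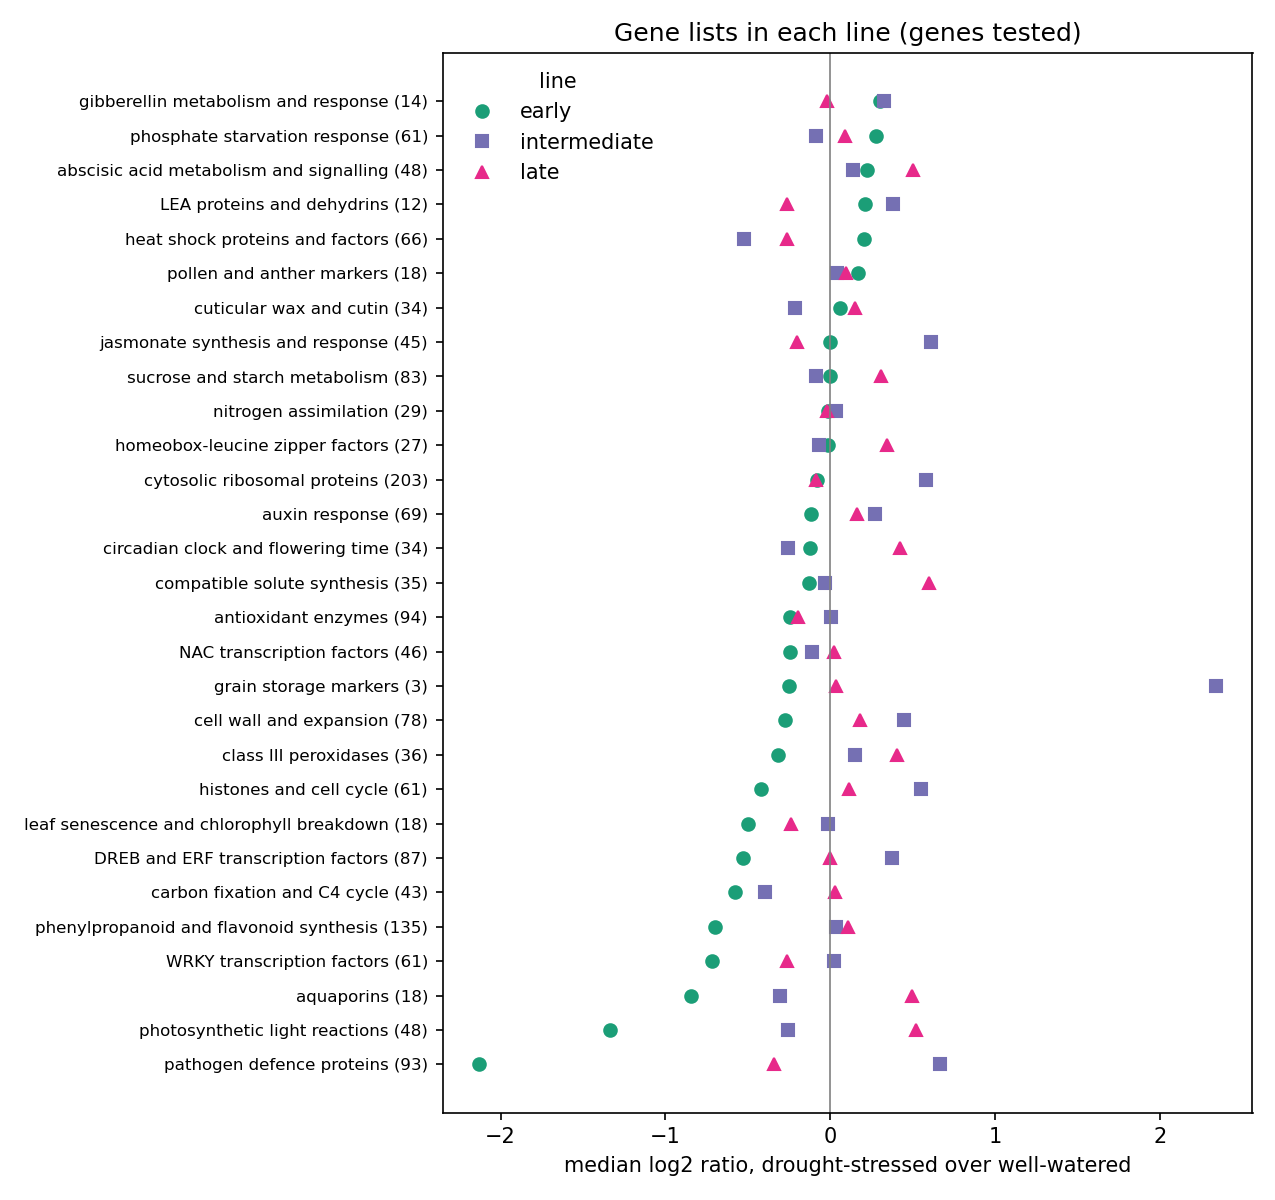
Median log2 ratio of drought-stressed over well-watered CPM (horizontal axis) for each of the 29 gene lists (vertical axis, number of tested genes in parentheses), 1 symbol per line. Pathogen defence stands at -2.13 in the early and 0.67 in the intermediate line, and the light reactions at -1.33 in the early and 0.52 in the late line.

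Lists tied to water deficit were not called over the 3 pairs. Without the early pair, camera at the preset correlation called the abscisic acid list higher (adjusted p = 0.0304), and without the late pair it called the aquaporins lower (adjusted p = 0.0169), but an estimated correlation in the same fits, tried after seeing the data, called neither (adjusted p = 0.8003 and 0.8831 with an estimated correlation). Of 48 genes of abscisic acid metabolism and signalling, 31 had a positive fold change (medians 0.22, 0.14 and 0.50 in the early, intermediate and late line; camera adjusted p = 0.123). The hydroxylase (LOC8073163) came closest to passing in that list (edgeR adjusted p = 0.054, adjusted over the list alone), followed by abscisic stress-ripening protein 1 (LOC8075331), with ratios of -2.81, -0.30 and -1.5. The receptor PYR1 (LOC8055151) had ratios of 1.30, 1.49 and 0.41. Only 12 of the 33 annotated late embryogenesis abundant proteins and dehydrins, which protect cells during drying, had enough counts to be tested, and their medians were 0.21, 0.38 and -0.26 (adjusted p = 0.608). Dehydrin COR410 (LOC8073921) had ratios of 0.56, 1.70 and -0.51. The 35 genes of compatible solute synthesis had medians of -0.13, -0.03 and 0.60 (adjusted p = 0.767), and their top member, trehalose-phosphate synthase 6 (LOC8055795), had 1.70, 1.49 and 1.24. The 18 aquaporins, which are water channels, had medians of -0.84, -0.31 and 0.50 (adjusted p = 0.608).

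Among sugar genes, cytosolic invertase 1 (LOC8071756), which splits sucrose, had ratios of 1.38, 1.74 and 1.85, and the sugar transporter SWEET1a (LOC110433964) had 4.07, 0.85 and 2.00. The sucrose and starch list of 83 genes had 50 positive members (camera adjusted p = 0.272). In the circadian and flowering list, CONSTANS-LIKE 3 (LOC8059668) had ratios of 1.62, 1.62 and 2.11 and the clock regulator PRR37 (LOC8070845) 2.71, 1.31 and 0.81 (list camera adjusted p = 0.537). LOC8079394, also described as CONSTANS-LIKE 3, had 31.2 CPM under drought and 134 when watered in the early line. It had 54.2 and 77.6 in the intermediate and 148 and 63.5 in the late line. LOC8073262, of the same description, was likewise lower in the early and intermediate lines and higher in the late line. NAC transcription factor 25 (LOC8067141) had 1.52, 1.36 and 1.31. The medians of 66 heat shock genes were 0.20, -0.52 and -0.26 (adjusted p = 0.123), and those of 203 cytosolic ribosomal protein genes -0.08, 0.58 and -0.09 (adjusted p = 0.182). Without the early pair, the preset correlation called the heat shock list lower (adjusted p = 2.29e-05) and the ribosomal protein (adjusted p = 0.00396) and cell wall (adjusted p = 0.0176) lists higher, while an estimated correlation called none of them (adjusted p = 0.8003, 0.8083 and 0.8003 with an estimated correlation). Pollen and anther markers, taken as a sign of tissue other than leaf, had medians of 0.17, 0.04 and 0.09 over 18 genes, and the 3 of 41 grain storage markers with enough counts to be tested had medians of -0.25, 2.34 and 0.03. Of these, a vicilin-like protein (LOC8073165) had 599 CPM under drought and 118 when watered in the intermediate line, 10.6 and 85.1 in the late line and 176 and 67.7 in the early line, so these few markers do not settle whether other tissue was present.

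The second comparison set the drought-stressed against the well-watered library within each line, which has no replicate check and no test. In the early line, anthocyanidin 5,3-O-glucosyltransferase (LOC8062148), an enzyme of anthocyanin pigment synthesis, had 1514 counts under drought and 0 when watered. This is 572-fold higher against a floor of 3 counts per library, with a lower limit of 464 from the 95% exact binomial interval. The gene overlaps another annotated gene, and it had 3079 and 1446 counts in the well-watered intermediate and late libraries. Its 0 may therefore be a failed estimate or reads assigned elsewhere. Pathogenesis-related protein PRMS (LOC8069055) had 319 CPM when watered and 0.21 under drought, a 1540-fold difference with a 95% exact binomial interval of 527 to 7468. An aspartyl protease family protein (LOC8071770) had 154 CPM against 0.14, and an extensin-like protein (LOC110429664), a cell wall component, 355 against 0.55. Chorismate mutase 2 (LOC8080609), at the branch to aromatic amino acids, was 65.3-fold higher under drought in the early line against the same floor (lower limit 52.5). Over all tested genes, 4014 were at least 2-fold higher and 4267 at least 2-fold lower in the early line, or 21.4% and 22.7%.

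In the intermediate line 2663 genes were at least 2-fold higher under drought and 2159 at least 2-fold lower. The myb-related protein Hv33 (LOC8069000), a transcription factor, had 185 counts under drought and 0 when watered, at least 57.0-fold higher, and cinnamate hydroxylase CYP73A100 (LOC8084483), of the phenylpropanoid pathway, had 23.1 CPM against 0.25. A pentatricopeptide repeat protein (LOC8072507) had 1747 counts under drought and 0 when watered. The largest falls in value were those of early light-inducible protein HV90 (LOC8060733, 24.8-fold lower, interval 17.4 to 36.5) and wall-associated receptor kinase 5 (LOC8056778, 21.9-fold lower, interval 11.6 to 46.3).

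In the late line 1768 genes were at least 2-fold higher under drought and 1215 at least 2-fold lower. Homeobox-leucine zipper protein HOX6 (LOC8062073) had 36 CPM under drought and 2.31 when watered (15.6-fold, interval 12.6 to 19.5), while its log2 ratios in the early and intermediate lines were -0.36 and -0.09. Amino acid permease 3 (LOC8076313) was 11.3-fold higher and EXORDIUM (LOC8074815), a cell growth protein, 11.4-fold higher. LOB domain-containing protein 42 (LOC8067521) was 28.6-fold lower under drought in the late line, ubiquitin ligase PUB23 (LOC8079848) 28.2-fold lower and plant cysteine oxidase 2 (LOC8066562), an oxygen sensor, 10.8-fold lower. The intervals cover counting error only. Genes listed at 0 in one library of a pair and at 100 counts or more in the other numbered 96 in the early, 7 in the intermediate and 4 in the late line, and a 0 in estimated counts can be a failed estimate. With a minimum mean of 5 CPM, the early line had 2371 genes at least 2-fold higher and 2263 lower, against 996 and 916 in the intermediate and 706 and 792 in the late line.

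The third comparison asked whether the lines share their drought ratios. Genes at least 2-fold higher in all 3 lines numbered 131, where independent lists would share 53.5, and 52 were at least 2-fold lower in all 3, against 31.7. With a mean of at least 5 CPM these were 40 against 11.14 and 13 against 10.97. Opposite changes were also more frequent than independent lists would give: 2121 genes (11.3%) were at least 2-fold higher in one line and at least 2-fold lower in another, against 1849, or 893 against 661 between early and late, 633 against 375 between intermediate and late and 1110 against 1065 between early and intermediate. The intermediate and late lines shared 119 lower genes, against 140. An excess in both directions may come from genes that vary more in any pair, so the overlap alone does not show a shared response to drought. Trehalose-phosphate synthase 6, cytosolic invertase 1, NAC transcription factor 25, 1 of the genes described as CONSTANS-LIKE 3 (LOC8059668) and the abscisic acid 8'-hydroxylase were among the genes higher in all lines. The metal-nicotianamine transporter YSL12 (LOC8056023) had 156 CPM under drought and 56.5 when watered in the early line, 295 and 52.3 in the intermediate line and 172 and 51.5 in the late line. The Pearson correlation of the ratios across genes was 0.105 for the early and intermediate lines, -0.010 for the early and late lines and -0.042 for the intermediate and late lines; the Spearman values were 0.104, 0.013 and -0.036. Genes are not independent replicates, so no p-value is given. Of the tested genes, 25.5% had the same sign in all 3 lines, against 23.8% for independent signs. Among the 1599 members of the gene lists, 248 were at least 2-fold higher in one line and at least 2-fold lower in another.

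The fourth comparison set the lines against each other over both water regimes. The 34 tested circadian and flowering genes had a median log2 difference of 0.002 between late and early (camera, preset correlation, adjusted p = 0.218). The 4 with the smallest p were named. Among them, 3 homologs of the rice florigen Hd3a, the mobile protein that starts flowering, were lower in the late than in the early line. LOC8069174 (chromosome 10, 3500240 to 3502320) had 77 and 66.1 CPM in the early line (watered, then drought), 9.03 and 13.2 in the intermediate line and 0 in both late libraries, at least 1999-fold lower than in the early line against a floor of 3 counts over the pair (edgeR adjusted p = 0.0269). LOC8075576 (chromosome 3, 62747942 to 62749918) had 74.9 and 75.0 CPM in the early, 2.74 and 16.4 in the intermediate and 0.66 and 0.27 in the late line (log2 difference -7.26 ± 1.11 SE, edgeR adjusted p = 0.0426). LOC8082981 (chromosome 9, 54962234 to 54964355) had 33.9 and 30.3 CPM, 4.86 and 3.28, and 3.09 and 1.00 (-4.15 ± 0.56, edgeR adjusted p = 0.040). The clock gene CCA1 (LOC8080836, chromosome 7, 4745544 to 4757846), a transcription factor that peaks at dawn, had 226 and 184 CPM in the early, 121 and 73.2 in the intermediate and 7.73 and 4.53 in the late line, and was lower in the late than in the early line (-5.11 ± 0.51, edgeR adjusted p = 0.0286) and than in the intermediate line (-3.99 ± 0.48, edgeR adjusted p = 0.0352). All 4 calls against the early line ended when either intermediate library was left out (edgeR adjusted p from 0.0855 to 0.101, log2 differences from -13.84 to -4.12). Those of LOC8075576 and LOC8082981 also ended without the late drought-stressed library (edgeR adjusted p = 0.0699 and 0.109) or the early drought-stressed one (0.0503 and 0.0525), and that of LOC8075576 without the early well-watered one (0.0537). A line left with a single library is fitted exactly, so the spread then comes from the other pairs. Without an intermediate library, the late minus early difference of LOC8069174 was -13.84 or -13.82, against -13.80 with all libraries. Genes described as FLOWERING LOCUS T differed by 0.35 (LOC8061952), -1.13 (LOC8054807) and -3.62 (LOC8080507), and RICE FLOWERING LOCUS T 1 (LOC8079504) by -2.58, none of them called. The Hd3a homologs belong to one family, between which the counting could split reads.

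**Figure D3:**
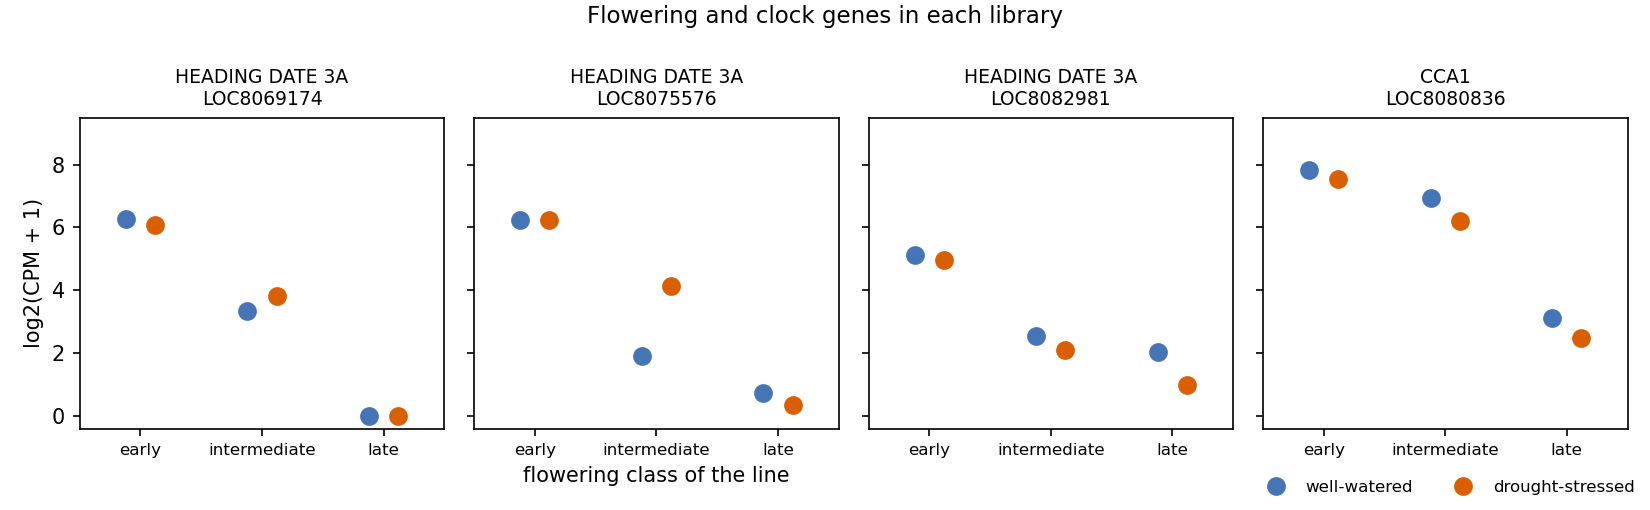
log2(CPM + 1) of 3 Hd3a homologs and CCA1 (vertical axis) in each line (horizontal axis), 1 point per library, coloured by water regime. For each gene both late libraries lie below both early libraries, and LOC8069174 is at 0 CPM in both late libraries.

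Over all genes, the late line had 206 genes higher and 225 lower than the early line, and 171 higher and 282 lower than the intermediate line. The intermediate line had 105 higher and 67 lower than the early line (edgeR, Benjamini-Hochberg at 0.05). On simulated counts, 29 of 291 calls between late and early were false, a share above that level. A neomenthol dehydrogenase (LOC8078895), a short-chain reductase of terpenoid metabolism, had 360 and 238 CPM in the intermediate line, 42.9 in both early libraries and 0 in both late libraries. Polyphenol oxidase I (LOC8057594), an enzyme of tissue browning, had 136 and 63.0 CPM in the intermediate line and 0 in the late line. Cysteine-rich receptor-like kinase 6 (LOC8074343) and basic leucine zipper 23 (LOC8055257) were at 0 in the late line as well, at least 1045-fold and 871-fold lower than in the early line. EGG APPARATUS-1 (LOC8081538) had 49.7 and 82.9 CPM in the late and 27.0 and 41.4 in the intermediate line, and 0 in both early libraries. Hydrophobic protein OSR8 (LOC8077254), cinnamoyl-CoA reductase 1 (LOC8074700), of lignin synthesis, and TFIID subunit 4 (LOC8079912) were also at 0 in the early line, and at least 209-fold, 418-fold and 743-fold higher in the late line. The iron-sulfur scaffold protein IscU (LOC8074615) and FKBP43 (LOC110436628) were at 0 in the intermediate line alone.

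One line was at 0 in both of its libraries for 136 of the 431 genes called between the late and early lines, 115 of 453 between late and intermediate, and 95 of 172 between intermediate and early. Of the genes higher in the late line, 38 were called against both other lines, and of those lower, 128 were. Independent lists would share 1.87 and 3.38. Simulated unchanged lines that share the late libraries had at most 2 in common. Such lines need not give lists of this size, so that simulation sets no expectation for the overlap. Part of the overlap may come from the shared late libraries. A line left with a single library is fitted exactly, so the calls with a library left out rest on the spread of the other pairs. Leaving out either intermediate library gave 0 calls in all 3 contrasts. Without the late drought-stressed library there were 87 higher and 102 lower between late and early, 78 and 104 between late and intermediate, and 316 and 231 between intermediate and early, where leaving out the late well-watered library gave 323 and 241. Without the early well-watered library the counts were 458 and 472, 962 and 1279, and 44 and 36 in the same order; without the early drought-stressed one, late against intermediate gave 889 and 1184 and intermediate against early 28 and 18. Leaving out both early libraries gave 1301 higher and 1585 lower between late and intermediate. With RLE size factors, 197 genes were higher and 224 lower in the late than in the early line, and with DESeq2 1339 and 1383. The transcript table gave 0 calls in each contrast, and limma-voom gave 0 between intermediate and early. With limma on log2(FPKM + 1), which changes the test, the added constant and the scaling together, 2611 genes were higher and 416 lower in the late than in the early line, and 2522 higher and 642 lower than in the intermediate line. With total counts in place of TMM in the edgeR fit, a scaling tried between lines after seeing the data, the median over all tested genes moved from 0.06 to 0.80 and from 0.13 to 0.84 on the log2 scale, so the differences given are relative to the bulk of the genes.

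Heat shock genes had lower values in the late line than in the other lines. The 66 members of that list, chaperones and their transcription factors, had a median log2 difference of -1.13 from the early line (4 members lower, 0 higher over all genes, and 24 adjusted over the list alone) and of -1.86 from the intermediate line (14 lower, 0 higher, and 37 adjusted over the list alone). The camera test of lists between lines was chosen after seeing the data, and it called this list lower in both contrasts with the preset correlation, but in neither with an estimated correlation (adjusted p = 0.946 and 0.653 with an estimated correlation). With the preset correlation, 1 list was called between late and early, 7 between late and intermediate and 8 between intermediate and early, and with an estimated correlation 0 in each. The power of the latter was not simulated, so its 0 calls decide nothing about these lists. The 7 were light reactions, higher in the late line (median difference 1.45), and heat shock, ribosomal proteins, defence, nitrogen assimilation, antioxidant enzymes and NAC transcription factors, lower. The 8 between intermediate and early were light reactions, lower in the intermediate line (-0.74), and lists higher in it. These were heat shock (1.10), ribosomal proteins, antioxidant enzymes, NAC and WRKY factors, histones and cell cycle, and jasmonate. Part of the difference between late and intermediate may thus lie in the intermediate line. The light reactions had a median difference of 0.43 between late and early and were not called. These lists are measured beside ribosomal RNA shares that differ between the same lines.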

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

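The ratios compared here come from 1 pair of libraries per line, so no difference between lines was tested. The test on the ribosomal RNA shares was chosen only after the result was seen.

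The pathogen defence list had medians of -2.13 in the early and 0.67 in the intermediate line, 2.79 apart on the log2 scale, and the light reactions list -1.33 in the early and 0.52 in the late line, 1.86 apart. For defence, 69 of 93 members were lower in the drought-stressed early library. Relative to each gene's mean over the 6 libraries, the list's median was 1.16 in the early well-watered library and -0.70 in the early drought-stressed one, against 0.46 and 1.07 in the intermediate and -0.28 and -0.35 in the late libraries, so both early libraries lie at the ends. The choice among the scalings tried is argued against as the cause. The median was -2.14 with RLE factors and -2.17 with ribosomal RNA, organelle and 3 unplaced rows removed. TMM and RLE lie close together, with median drought differences of 0.017 and 0.003 over all tested genes. A scaling far from them was not tried for this list. The ribosomal RNA shares of the early libraries differ by 0.71 percentage points, too little for such a shift. A response of the early line to drought stays open, as untested, and so does a difference between the plants of the pair that has nothing to do with water, since each library is the only one of its kind.

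Genes listed at 0 counts in one early library and at 100 or more in the other numbered 96, of which 70 were at 0 under drought, against 7 and 4 genes in the intermediate and late pairs. Sampling of few reads is argued against as the cause: the expected count in the library at 0 was 90.1 or more, with a median of 179, where sampling would need counts near 0. The choice of genes alone bounds that count at 88.3. Over all tested genes, counting error would leave 2.24e-26 such genes, against the 96 found, a value near 0 set by the limit of 100 counts. Both values speak only of reads counted independently. These counts are estimates, so a failed estimate stays open. Reads lost to overlapping genes would raise the share that overlaps another annotated gene, which was 5.2% (95% exact interval 1.71% to 11.74%) against 7.79% of all tested genes, and the interval reaches the 11.68% set as the limit, so this stays open. A shared response to drought may be part of it: 68.1% moved the same way in the intermediate pair (95% exact interval 57.5% to 77.5%), but 44.9% did in the late pair. The interval treats genes as independent. Over all tested genes, 772 were at least 2-fold higher and 841 at least 2-fold lower in both the early and intermediate pairs, against 1110 opposite. Moving the same way was thus not limited to the genes at 0. Plants of different genotype in the early pair cannot be told apart from the rest with these counts: of 153 genes that are on in one and off in the other of the intermediate and late lines, 94 are expressed in the early pair, and 6.38% of these split it (95% exact interval 2.38% to 13.4%), against 0% of 83 expressed such genes for the intermediate pair (0% to 4.35%) and 1.37% of 73 for the late pair (0.035% to 7.40%), and the intervals overlap.

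Other genes were at least 2-fold higher in one line under drought and at least 2-fold lower in another, and where a library is at 0 the size depends on the prior count of 2. Named for the early line, these were anthocyanidin 5,3-O-glucosyltransferase (LOC8062148), with ratios 11.45 apart, GDSL esterase/lipase (LOC8063491), 10.19 apart, receptor kinase PERK12 (LOC8058218), 10.33 apart, and chorismate mutase 2 (LOC8080609), whose highest and lowest ratios differ by 9.55. Named for the intermediate line, these were sugar carrier protein C (LOC8065140), 9.25 apart, cytochrome P450 CYP73A100 (LOC8084483), 8.25 apart, wall-associated receptor kinase 5 (LOC8056778), 5.74 apart, and heavy metal-associated isoprenylated plant protein 47 (LOC8055419), 8.51 apart. Named for the late line, the tropomyosin-like gene (LOC8086147) differed by 7.72, EXORDIUM (LOC8074815) by 5.40, amino acid permease 3 (LOC8076313) by 7.38 and LOB domain-containing protein 42 (LOC8067521) by 5.83. Ubiquitin ligase PUB23 (LOC8079848) differed by 6.72, carboxylesterase 8 (LOC8054333) by 8.03 and plant cysteine oxidase 2 (LOC8066562) by 7.07 on the log2 scale.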

How the results depend on the processing

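The removal of ribosomal RNA and organelle rows, the removal of genes at 0, the fit without both early libraries and the estimated correlation with a pair left out were chosen only after the data were seen. The cause of the changes below was not tested. Where a single library was left out, its line is fitted exactly, so the spread comes from the other pairs. The count of 0 drought genes held in each alternative except DESeq2's Wald test (20 higher, 5 lower), including no replicate block (0 higher, 0 lower) and each pair left out. All 10 splits of the 6 libraries into 3 and 3 gave 0 genes, the real value and the highest other both being 0, and 10 splits are too few for a share under 0.05. The counts between lines moved by under 1.5 times with RLE factors, a mean of 10 counts, a fit that is not robust and ribosomal RNA and organelle rows removed.

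In the order late against early, late against intermediate and intermediate against early, the counts between lines (higher, then lower) were 1339 and 1383, 1336 and 1682, 1308 and 992 with DESeq2. limma-voom gave 289 and 473, 282 and 651, 0 and 0. Without a low-count filter they were 381 and 418, 354 and 480, 251 and 189. With log2(FPKM + 1) they were 2611 and 416, 2522 and 642, 315 and 134, and with log2(TPM + 1) 1463 and 407, 1781 and 605, 303 and 184. The transcript table gave 0 in each. Without a regime term they were 379 and 452, 399 and 558, 264 and 173. Leaving out 1 library gave 0 to 458 and 0 to 472, 0 to 962 and 0 to 1279, 0 to 323 and 0 to 241, with 0 when either intermediate library was left out. Without both early libraries, late against intermediate gave 1301 and 1585.

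Within lines, a mean of at least 5 CPM gave 2371 and 2263 genes (early), 996 and 916 (intermediate) and 706 and 792 (late), and FPKM + 1 gave 2541 and 2299, 1063 and 562, 1049 and 476. The other scalings, prior counts and the removal of genes at 0 moved these counts by under 1.5 times. The early and intermediate correlation was 0.184 with at least 5 CPM and 0.142 without genes at 0, the intermediate and late one -0.086 and -0.067, and the early and late one turned to 0.0028 without genes at 0. Genes changed in all 3 lines (higher, lower) were 40 and 13 with at least 5 CPM, 424 and 249 at 1.5-fold, 21 and 6 at 4-fold, and 75 and 27 without genes at 0.

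Among the 5 lists called, an estimated correlation gave an adjusted p of 0.942 for each, and fry 0.929 (light reactions, defence, WRKY), 0.662 (carbon fixation) and 0.524 (antioxidant). Without a low-count filter, defence had 0.301, WRKY 0.0685 and antioxidant 0.116; with no replicate block antioxidant had 0.127, the one call the block changed; without ribosomal RNA rows it had 0.0518. With each pair left out, adjusted p ran from 1.05e-07 to 0.52 for light reactions, 7.65e-12 to 0.369 for defence, 0.0029 to 0.112 for carbon fixation, 0.000315 to 0.329 for WRKY and 0.0431 to 0.479 for antioxidant; without the early pair light reactions (0.52) and defence (0.369) turned to higher. Not called with all pairs, abscisic acid (0.0304 to 0.479), heat shock (2.29e-05 to 0.771), cell wall (0.0176 to 0.972) and ribosomal proteins (0.00396 to 0.286) were called without the early pair, heat shock lower and the others higher, and aquaporins (0.0169 to 0.492) were called lower without the late pair. With an estimated correlation, 0 of 29 lists were called with any pair left out: the adjusted p of the 5 lists was 0.883 each without the late and 0.83 each without the intermediate pair, and without the early pair 0.8003 for carbon fixation, WRKY and antioxidant, 0.9325 for light reactions and 0.8604 for defence, both on the higher side. The power of camera with an estimated correlation was not simulated, so the absence of calls does not count against these lists. For lists, 5 to 7 of the uncalled directions changed when a pair was left out. Not all of the 41 gene and contrast pairs named between lines were called with all libraries. Each pair that was called lost its call when either intermediate library was left out, and 0 turned. With limma-voom, 12 of the called pairs lost their call. Depth limits low genes most, with a floor of 0.068 CPM in the late and 0.207 CPM in the early drought-stressed library.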

Other observations

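The test on the hour of harvest was chosen only after the result was seen.

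Of 5 tested genes matched by name to the synthesis of the cyanogenic glucoside dhurrin, which deters herbivores and stores nitrogen in sorghum, 2 had higher values under drought in all lines. They were chosen after their values were seen. Cyanohydrin beta-glucosyltransferase (LOC8060874, chromosome 1, 1152299 to 1154106), its last enzyme, had 225 CPM under drought and 36.2 when watered in the early line, 62.9 and 21.7 in the intermediate line and 5.23 and 1.75 in the late line. 4-hydroxyphenylacetaldehyde oxime monooxygenase (LOC8060873, chromosome 1, 1048557 to 1050683), which acts before it, had 215 and 6.64, 15.0 and 3.24, and 5.37 and 2.61 CPM. Neither passed in edgeR (log2 fold changes 1.92 and 2.69, adjusted p = 0.984 each), and DESeq2 called the glucosyltransferase (DESeq2 adjusted p = 0.0127). A neighbouring oxime monooxygenase-like gene (LOC8060872, chromosome 1, 1031540 to 1033883) had 2.97 CPM under drought and 50.8 when watered in the early line. Another oxime monooxygenase-like gene (LOC8057306) had log2 ratios of -4.27, -0.60 and 0.75 in the early, intermediate and late line, and a tyrosine N-monooxygenase-like gene (LOC8061994) -0.42, 0.53 and 1.46, so the group does not move as one. NDR1/HIN1-like protein 13 (LOC8055279), named for a resistance protein, had 3.45 and 119 CPM in the early line, 20.8 and 176 in the intermediate line and 30.6 and 53.4 in the late line (DESeq2 adjusted p = 0.028).

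CCA1 peaks at dawn, so lines harvested at different hours might differ in it without differing in their clock. The 9 tested genes matched by name as evening or daytime clock genes had a median log2 difference of 0.40 between the late and the early line (96.1% interval of the median from its ranks, -1.39 to 2.02). Of these 9 genes, 5 were higher and 4 lower, while CCA1 differed by -5.11. Among the 9, PRR1 (LOC8072479) had 1.10 and 10.2 CPM in the early and 12.4 and 16.9 in the late line. PRR37 (LOC8070845) and PRR73 (LOC8084889) were lower in the late line by 1.57 and 1.39 on the log2 scale. A median over genes that go both ways decides nothing, and an hour of harvest and a difference between lines cannot be told apart here, because each line has its own pair and no hour is given for either.

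A different hour between the regimes stays open too and was not tested. CCA1 was lower under drought in each line (log2 ratios -0.29, -0.72 and -0.76 in the early, intermediate and late line), and PRR1 (3.13, 1.52 and 0.44) and PRR37 (2.71, 1.31 and 0.81) were higher in each, as a later hour under drought might give. The evening genes as a list went both ways, with medians of 0.76, -0.20 and 0.16. Without PHOTOPERIOD-INDEPENDENT EARLY FLOWERING 1, which entered the list by its name alone, these medians were 0.34, -0.11 and 0.30, and that between the late and early lines 0.50.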
